A study of Homo sapiens with 4 samples.

How the data were processed

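Total RNA of MDA-MB-231 cells was labelled with Cy3 and hybridised to Agilent 1-colour arrays, per the labels' protocols, for 2 negative control and 2 ASH2L sh3 knockdown samples that the series describes as biological replicates. What the negative control cells carried is not given in the sources used here. The 4 arrays lay on 1 slide and were scanned together, per the file headers, with the controls at the first positions and the knockdown at the last, so that position on the slide and group cannot be told apart. A single hairpin was profiled, so that effects of ASH2L loss and of that hairpin on other transcripts cannot be told apart either.

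The deposited scanner files hold spot intensity on a linear scale, made with Agilent Feature Extraction 11.0.1.1, per the file headers and the submitters' processing notes. The processed signal is background-subtracted and spatially detrended, per the file headers, and not scaled between arrays. The value table deposited by the authors holds a ratio: each processed signal divided by close to its array's 75th percentile, linear and not log transformed. This was found by setting each column against its array's scanner values, where 98.0% to 98.5% of probes gave the same divisor within 0.1%. Genes are not centred in it, the column medians are 0.393 and 0.382 (control) and 0.392 and 0.389 (knockdown), and scale, centring and direction were all settled. Its 22936 probes are each well above background on at least 1 array.

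Each array held 44495 spots and 34127 different probes that are not controls, 999 of them with 10 spots each. The files hold accessions and no gene names. Accessions without versions were matched to symbols in a RefSeq table of GRCh38.p14, which named 25771 probes (75.5%, 19740 symbols) and left 8356 under their own accession or identifier. The array design was annotated on another build, so that no coordinates are given.

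Values were log2 of the processed signal minus each array's 75th percentile over probes that are not controls. Spots with a non-uniformity or population outlier flag were left out and spots of 1 probe averaged. No spot was saturated (0 on each array). Probes well above background on both arrays of at least 1 group were kept (21253), and each gene was represented by its brightest kept probe, which gave 17135 genes, 13783 of them with a symbol and 3447 with several kept probes. Of 329 called genes with several probes, 27 had a probe of opposite sign, and 0 genes were called both ways. Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with group as the only term, on 2 residual degrees of freedom plus 2.78 prior ones, and Benjamini-Hochberg adjustment over all genes at 0.05. The replicates differed by a standard deviation of 0.278 (control) and 0.305 (knockdown) on the log2 scale, and 0% of spots had identical values. Spike-in transcripts gave a slope of 0.885 and 0.875 on the control arrays and 0.865 and 0.855 on the knockdown arrays, outside the range that the scanner software accepts on all 4 arrays, per the file headers. For a gene above background in 1 group alone, the bound is the bright group's mean minus the dim group's mean of, per array, the higher of its own value and the lowest value among probes well above background on that array.

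The 27 gene lists, the tests of genes and of lists, the rule for named genes and the processing alternatives other than a common signal bar for all arrays were fixed before the data were examined. The tests of explanations, the BMP list and the test of neighbouring genes came afterwards, and among them the permutation within bins of like brightness and the tests of luminal markers and of the dimmer genes were chosen after the results they bear on had been seen. The 27 lists hold 939 genes, of which 924 were on the array and 814 were tested. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation, camera on ranks and fry as alternatives. Camera sets the members of a list against all other genes tested, so that its direction is relative to them. Under normexp with the 75th percentile the median of all genes was 0.13, so that a list with a median near 0 can pass downwards there. With the estimated correlation 0 of the 7 calls held. That test rests on the 2 residual degrees of freedom alone, so that few lists can pass it whatever their correlation. Basal markers, for example, had an estimated correlation of −0.082, below the preset value, and their camera p rose from 0.00516 to 0.0992. Endothelial markers also lay below the preset value (−0.067). For these lists a call lost under it therefore does not show that correlation between members had made the call. The other called lists lay above it, at 0.099 (interferon-stimulated), 0.14 (junction), 0.20 (chemokine), 0.41 (cholesterol) and 0.46 (histone). For them, correlation between members and the few degrees of freedom cannot be told apart as the reason for the lost call. The named genes are ASH2L and other COMPASS members past the threshold, the 10 largest rises and 10 largest falls among genes past the threshold, above background on all 4 arrays, separated between groups and with a gene symbol, the 4 members of each list with the lowest unadjusted p, and the 3 largest bounds in each direction. Genes taken in another way are said to be so. Some genes that the rule names are not reported here. Figures were drawn with matplotlib 3.10.9.

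The procedure was tested on simulated data for the 17135 genes with the spread of these arrays. With 200 changed genes, 0 of 50 changed by a log2 of 0.5 were found, 22 of 50 at 1, 45 of 50 at 2 and 50 of 50 at 3, with 7 false calls. With 3000 changed genes, 3.99% of 1654 calls were false and 94.4% of changes of 2-fold or more were found. Under camera 4 of 200 unchanged lists had a p under 0.05. Genes were simulated as independent of each other, so that the error of camera on lists whose members vary together was not tested.

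The alternatives were quantile normalization, the median in place of the 75th percentile, scaling on 8 of 10 spike-in probes, normexp background correction (offset 50) with the 75th percentile or quantiles, no filter on dim probes, a filter on all 4 arrays, every probe on its own, the mean of a gene's probes, flagged spots kept, the deposited value table, eBayes with a trend and robust settings, a replicate block, each array left out in turn and an adjusted p under 0.10. Added afterwards was 1 scaled signal bar for all arrays, the highest of the arrays' lowest values among probes well above background, used to count detected probes and, for the dimmer genes, as the filter and as a floor under all values. The scanner files used here hold no mean signal, so that normexp used the median signal and the median local background. With an array left out, the lone array of its group is assumed to vary like those of the other group.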

Results

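RNA levels were measured in MDA-MB-231 cells, an established triple-negative breast cancer line that lacks the oestrogen, progesterone and HER2 receptors. The series compared negative control cells with cells carrying a short hairpin RNA (sh3) against ASH2L, with 2 biological replicates in each group and 1 Agilent 1-colour array per replicate. ASH2L is a core subunit of the COMPASS family of complexes, which methylate lysine 4 of histone H3, and the series title asks whether it takes part in invasion and migration of these cells. The 75th percentile of the processed signal was 572 and 503 on the control arrays and 389 and 410 on the knockdown arrays, so that the knockdown arrays were the dimmer ones. Of 34127 probes, 65.2% and 62.6% were well above background on the control arrays and 61.4% on each knockdown array. Across the 17135 genes tested, Pearson's r was 0.996 between the control arrays, 0.995 between the knockdown arrays and 0.984 to 0.985 between groups (genes are not independent replicates). Differences are given as log2 of knockdown minus control, each with its standard error (SE) and n = 2 per group, and the small number of arrays limits their precision.

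ASH2L itself was lower on both knockdown arrays than on both control arrays. Its single probe, A_23_P134827, had scaled log2 signals of 1.29 and 1.37 in the controls and −0.73 and −0.86 in the knockdown, a log2 difference of −2.13 (SE 0.105), or 4.36-fold lower (limma adjusted p = 0.00573). Among the 21 measured subunits of COMPASS and related MLL complexes, 2 rose, ASH2L alone fell, and 18 did not pass the test. The histone methyltransferase SETD1A rose by 0.63 (SE 0.101) and the scaffold protein MEN1 by 0.57 (SE 0.0967, both of its probes past the threshold). The list had a median of 0.15 and did not pass as a set (camera adjusted p = 0.256), and adjusted over the list alone the same number passed, 2 up and 1 down. WDR5, a shared core subunit, differed by 0.37 (adjusted p = 0.0920). The calls of SETD1A and MEN1 ended when either knockdown array was left out and under spike-in scaling, that of MEN1 also with the median in place of the 75th percentile, and the ASH2L call ended without control replicate 1 (−2.17, adjusted p = 0.0780), without control replicate 2 (−2.08, adjusted p = 0.113) and with no filter on dim probes (adjusted p = 0.0878).

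**Figure D1:**
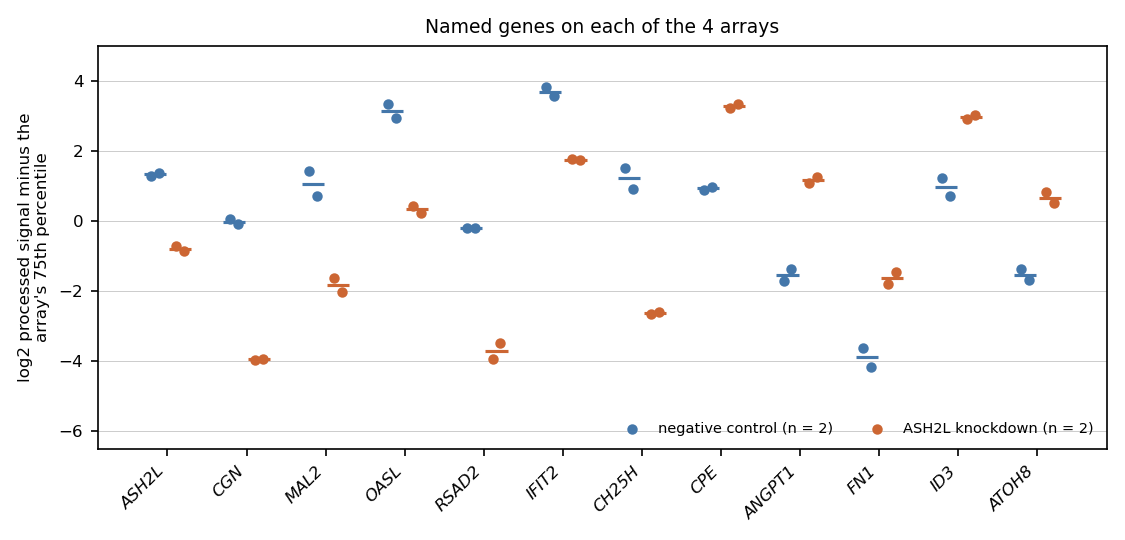
Log2 processed signal minus the array's 75th percentile (vertical axis) of 12 named genes on each of the 4 arrays, with points for arrays and short lines for the mean of each group (n = 2). ASH2L lies at 1.29 and 1.37 in the controls and at −0.73 and −0.86 in the knockdown. For each gene shown the knockdown arrays lie on 1 side of both control arrays, which the rule for the largest rises and falls required.

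In all, 770 genes were higher and 973 lower in the knockdown at an adjusted p under 0.05, together 10.2% of the genes tested, and 44.2% of the calls were rises. Of these, 174 rose and 496 fell by 2-fold or more, against 251 and 608 without knockdown replicate 1 and 236 and 560 without knockdown replicate 2 over the same genes, 133 and 919 with spike-in scaling, 49 and 161 with normexp background correction before the 75th percentile and 40 and 190 with normexp and quantiles. With a knockdown array left out the filter also kept genes above background on the 1 remaining knockdown array that were not among those tested on 4 arrays, and with these the counts were 495 rises and 608 falls without replicate 1 and 608 and 561 without replicate 2. Unadjusted p was under 0.05 for 5125 genes. The split between rises and falls depended on the setting. Rises made up 29.5% of the calls with the median in place of the 75th percentile, 14.6% with spike-in scaling and 73.4% with normexp background correction before the 75th percentile. The prior degrees of freedom of limma were 4.94, infinite and 8.41 in these fits, against 2.78 in the main fit. Their numbers of calls therefore differ by the variance model as well as by the scaling or background correction. All calls ended without control replicate 1, without control replicate 2 and with no filter on dim probes (0 calls, 7767 genes at an unadjusted p under 0.05). In these fits 1, 3 and 1 of the 1743 called genes changed sign. The fits share their values with the main fit that chose these genes, so that few signs could change. Limma had 1.90, 1.75 and 1.58 prior degrees of freedom there, against 2.78 in the main fit and 5.22 and 5.03 without knockdown replicates 1 and 2. The lost calls therefore do not show that the differences themselves rested on the control arrays, and the kept signs do not show that they did not.

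**Figure D2:**
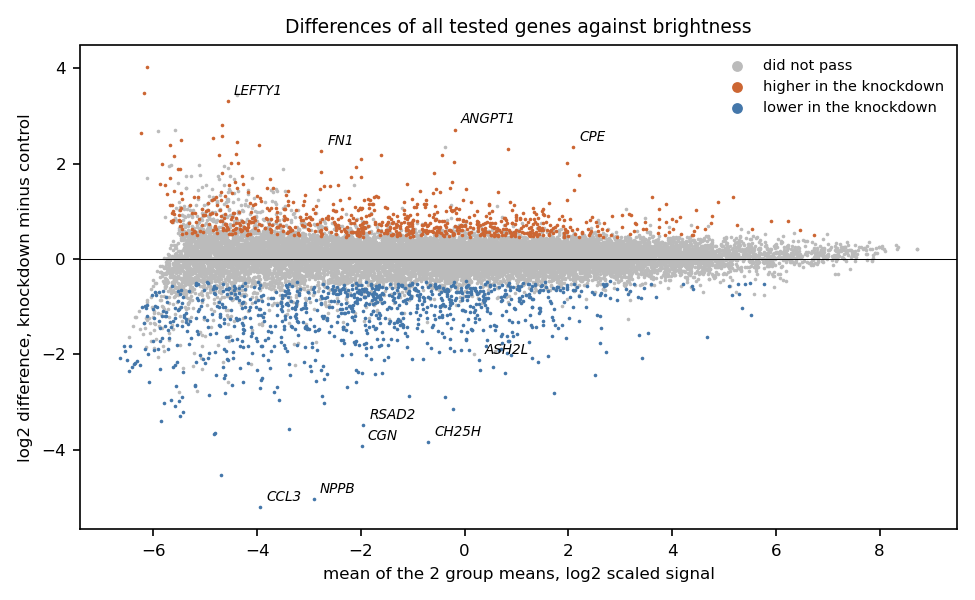
Log2 difference of knockdown minus control (vertical axis) against the mean of both group means of the scaled log2 signal (horizontal axis) for the 17135 genes tested, with genes past an adjusted p of 0.05 in colour. Of the 770 rises 174 were of 2-fold or more, and of the 973 falls 496, against 251 rises and 608 falls without knockdown replicate 1 and 236 rises and 560 falls without knockdown replicate 2 over the same genes.

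Among genes well above background on all 4 arrays, the largest rise was that of ANGPT1, a ligand of the TEK receptor, by 2.71 (SE 0.152), followed by the vitamin B12 binder TCN1 by 2.40 (SE 0.229), the prohormone-processing enzyme CPE by 2.35 (SE 0.103) and fibronectin, FN1, by 2.26 (SE 0.231). The transcription factor ATOH8 rose by 2.19, the hedgehog ligand IHH by 2.11, DMBT1 by 2.03, the granin SCG2 by 2.02, the helix-loop-helix inhibitor ID3 by 2.01 and the dopamine receptor DRD2 by 2.01. Adjusted p lay between 0.00573 for CPE and 0.04999 for DMBT1, whose call ended under several other settings. The order of the rises depended on the background correction: with normexp and quantiles SCG2 differed by 0.50, DRD2 by 0.57, TCN1 by 0.80, FN1 by 1.11 and IHH by 1.25. The largest falls reported here were of the tight junction protein cingulin, CGN, at −3.92 (SE 0.104, 15.1-fold), the cholesterol 25-hydroxylase CH25H at −3.84 (SE 0.214) and the antiviral enzyme RSAD2 at −3.49 (SE 0.173). PI16 fell by 3.14, ACOXL by 3.02, the transporter family member SLC7A4 by 2.95, the apical sorting protein MAL2 by 2.90, TMEM45B by 2.88 and the interferon-induced OASL by 2.81. With normexp and the 75th percentile CGN fell by 2.48, RSAD2 by 2.17, ACOXL by 1.56 and SLC7A4 by 1.01. Both knockdown arrays lay beyond both control arrays for each of these genes, which the rule that chose them required.

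Some genes were measured above background in 1 group alone, and their differences are given as bounds. These hold for the processed signal and do not include sampling error. LEFTY1, an antagonist of NODAL signalling, was at least 7.80-fold higher in the knockdown and AZU1 at least 4.93-fold. STON1 was 4.54-fold higher, where the bound equals the estimated difference (a log2 of 2.18). The natriuretic peptide gene NPPB was at least 32.1-fold lower in the knockdown (both of its probes passed), the chemokine CCL3 at least 16.8-fold and the chemokine CCL5 at least 7.96-fold. These bounds rest on the processed signal, and with normexp and quantiles the log2 differences were 0.92 (LEFTY1), 0.48 (AZU1), 0.39 (STON1), −2.36 (NPPB), −1.78 (CCL3) and −1.11 (CCL5, −0.85 with normexp and the 75th percentile). Of the tested genes, 443 were well above background in the controls alone, of which 140 were called lower, and 41 in the knockdown alone, of which 31 were called higher. The bound was over 1-fold for 121 of the former and 31 of the latter calls, and the other called falls have no fold. Among all probes such an imbalance depended on the rule for detection. By the scanner's calls 571 probes were above background in the control arrays alone and 51 in the knockdown arrays alone. With 1 scaled signal bar for all arrays, a comparison chosen after the data were seen, these were 234 and 225. The 140 and 31 calls were not counted again under that bar.

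Epithelial junction genes were lower in the knockdown. Of 28 measured members, 17 fell, 1 rose and 10 did not pass, with a median of −1.02 (camera adjusted p = 2.79e-12), and adjusted over the list alone 19 fell and 1 rose. With an estimated correlation the set's adjusted p = 0.586, while fry, which asks whether members move on balance 1 way, gave an adjusted p of 0.0331. The median was −0.47 with normexp and the 75th percentile and −0.65 with normexp and quantiles, and the set passed under both. Besides CGN and MAL2, E-cadherin (CDH1) was at least 5.39-fold lower, being above background in the controls alone, and the serine protease inhibitor SPINT1 fell by 2.34 (SE 0.108), with 1 of 2 knockdown arrays above background. The membrane protease ST14 fell by 1.32 (SE 0.106). With normexp and the 75th percentile CDH1 differed by −0.48, SPINT1 by −0.52 and ST14 by −0.52. Basal breast markers also passed (2 of 11 fell and 0 rose, median −0.22, camera adjusted p = 0.0199, and adjusted p = 0.586 with an estimated correlation), and this call ended without knockdown replicate 1 (adjusted p = 0.0969). Their median was −0.47 with spike-in scaling and −0.37 with quantile normalization. Among them TRIM29 fell by 2.33 (SE 0.204). LAMB3 differed by −0.43 and FOXC1 by 0.38, and neither passed. Adjusted over the list alone, 3 basal markers fell and 1 rose. Of 17 luminal markers 3 fell and 1 rose, with a median of −0.32 (camera adjusted p = 0.154), or 6 and 4 adjusted over the list alone. AGR2 fell by 2.10 (SE 0.222), SPDEF by 1.46 (SE 0.174) and TFF1 by 0.86 (SE 0.114), whereas GATA3 rose by 0.67 (SE 0.122). With normexp and the 75th percentile SPDEF differed by −0.58 and TFF1 by −0.50, and the luminal list passed downwards (adjusted p = 0.0244, median −0.05).

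Mesenchymal genes went both ways. Of 26 measured members of the mesenchymal and EMT (epithelial-mesenchymal transition) list, 5 rose and 2 fell, with a median of 0.12 (camera adjusted p = 0.545), and adjusted over the list alone 7 rose and 2 fell. FN1 and the actin-binding protein TAGLN rose, TAGLN by 0.90 (SE 0.0982). The collagen gene COL6A2 fell by 0.80 (SE 0.105), and COL1A1 was at least 2.52-fold lower, above background in the controls alone. The sign of COL1A1 turned under normexp background correction with the 75th percentile.

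Interferon-stimulated genes, the antiviral genes switched on by interferon signalling, were lower in the knockdown. Of 46 measured members, 19 fell, 2 rose and 25 did not pass, with a median of −0.76 (camera adjusted p = 8.01e-09), and adjusted over the list alone 27 fell and 4 rose. With an estimated correlation the set's adjusted p = 0.586, and by fry it was 0.0331. With normexp the set passed at smaller medians, −0.28 with the 75th percentile and −0.37 with quantiles. RSAD2 and OASL are members of this list, as are the exonuclease ISG20 at −2.42 (SE 0.115) and the RNA-binding protein IFIT2 at −1.94 (SE 0.122, its other probe at −2.29). Chemokines and cytokines were lower as well, with 13 falls and 1 rise among 27 measured members, a median of −0.84 (camera adjusted p = 1.19e-07) and, adjusted over the list alone, 15 falls and 2 rises. This set's adjusted p = 0.586 with an estimated correlation and 0.107 by fry. Its median was smaller, at −0.40 with no filter on dim probes, −0.50 with the filter on all arrays and −0.45 under each normexp setting. Besides CCL3 and CCL5, CXCL16 fell by 1.90 (SE 0.155) and CCL26 by 1.79 (SE 0.111), and they differed by −0.78 and −0.83 with normexp and the 75th percentile. Of 26 measured NF-kB target genes, 2 fell and 1 rose, with a median of −0.02 (camera adjusted p = 0.0867). This list passed downwards by fry (adjusted p = 0.0331), with normexp and the 75th percentile (adjusted p = 0.00207, median −0.08) and with no filter (adjusted p = 0.00657), and its median was −0.27 with spike-in scaling, where it did not pass (adjusted p = 0.337). The cytokine LTB fell by 1.54 (SE 0.139) and the syndecan SDC4 by 0.67 (SE 0.109), while the apoptosis inhibitor BIRC2 rose by 0.74 (SE 0.133). CFLAR differed by −0.45 and did not pass (adjusted p = 0.0557), with probes of both signs. Adjusted over the list alone, 7 NF-kB target genes fell and 3 rose.

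**Figure D3:**
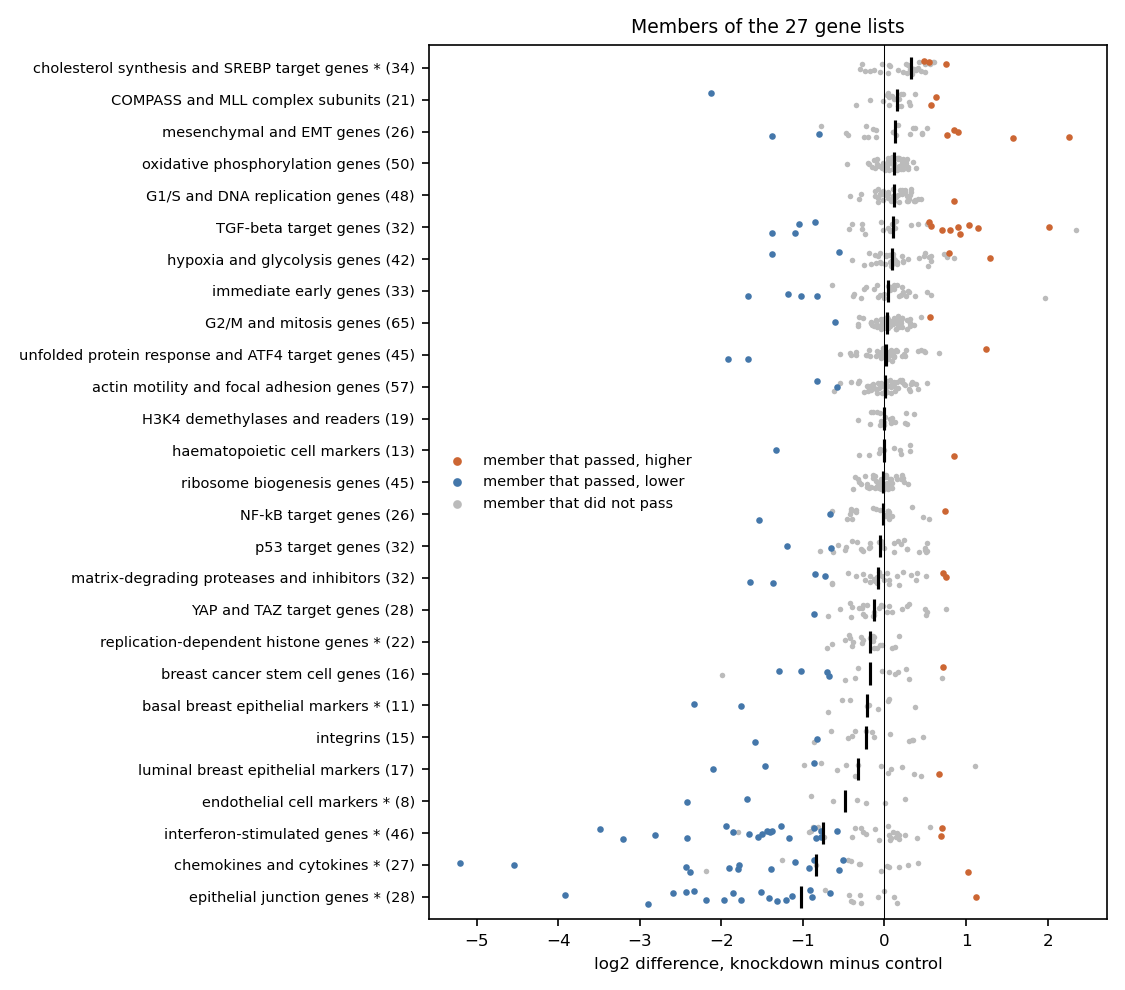
Log2 difference of knockdown minus control (horizontal axis) of each measured member of the 27 gene lists (vertical axis, number of members measured in brackets), with the median of each list as a black line. Colour marks members past an adjusted p of 0.05 and an asterisk marks the 7 lists past an adjusted camera p of 0.05, among which junction genes, at a median of −1.02, lie lowest.

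The lists that bear on invasion and movement, of proteases, integrins and actin genes, did not pass as sets. Of 32 measured matrix-degrading proteases and inhibitors, 4 fell and 2 rose, with a median of −0.08 (camera adjusted p = 0.220), or 4 and 3 adjusted over the list alone. The plasminogen activator PLAT fell by 1.64 (SE 0.228) and the metalloprotease inhibitor TIMP4 by 1.36 (SE 0.127), and the membrane inhibitor RECK rose by 0.71 (SE 0.0923), although its other probe differed by 0.08. Of 15 integrins, 2 fell and 0 rose, with a median of −0.22 (camera adjusted p = 0.0877). ITGB4, the hemidesmosome subunit, fell by 1.59 (SE 0.219) and ITGB3 by 0.83 (SE 0.150). ITGB7 at −0.87 and ITGB1 at 0.34 did not pass over all genes, and adjusted over the list alone 6 integrins fell and 3 rose. Of 57 actin motility and focal adhesion genes, the cofilin CFL2 fell by 0.83 (SE 0.159) and the actin bundler FSCN1 by 0.59 (SE 0.0926). RAC2 at −0.41 did not pass by its brightest probe, while its other probe, at −0.60, did, and LIMS2 at −0.54 did not pass. The median of that list was 0.01, its mean −0.01 and its test pointed downwards (camera adjusted p = 0.545), and 0 members passed adjusted over the list alone. With normexp and the 75th percentile the proteases (camera adjusted p = 0.0212, median −0.02) and the actin genes (camera adjusted p = 0.009997, median −0.02) passed downwards. The median of all genes was 0.13 there, so that these lists lay below the other genes while their own medians stayed near 0. Integrins passed downwards with no filter (camera adjusted p = 0.0495), and their median was −0.30 without knockdown replicate 2.

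Among TGF-beta target genes, 9 rose and 4 fell of 32 measured, with a median of 0.10 (camera adjusted p = 0.434), or 11 and 5 adjusted over the list alone. ID3 and TAGLN rose, as did PMEPA1 by 0.93 (SE 0.0930, its other probe at 0.59), whereas COL1A1 was lower. Of 28 YAP and TAZ target genes the kinase NUAK2 alone passed, at −0.87 (SE 0.109), with a list median of −0.13 (camera adjusted p = 0.176). The list passed downwards with normexp and the 75th percentile (adjusted p = 0.00787), with no filter (adjusted p = 0.0324) and without control replicate 1 (adjusted p = 0.0183, median −0.18). IGFBP3 at 0.76, GADD45B at 0.50 and F3 at −0.69 did not pass over all genes, and adjusted over the list alone 4 members rose and 4 fell. Of 33 immediate early genes 4 fell and 0 rose, over all genes and over the list alone. The phosphatases DUSP1 and DUSP5 fell by 1.18 (SE 0.136) and by 0.83 (SE 0.0952), and the transcription factor KLF4 fell by 1.02 (SE 0.117). ATF3 fell by 1.68 (SE 0.103), but 1 of its 4 probes differed by 0.35, and the mean of its probes by −0.85. The median of that list was 0.04, its mean −0.05 and its test pointed downwards (camera adjusted p = 0.387). Of 16 breast cancer stem cell genes 4 fell and 1 rose, with a median of −0.18 (camera adjusted p = 0.119), or 7 and 2 adjusted over the list alone. This list passed downwards by fry (adjusted p = 0.0331), with normexp and the 75th percentile (adjusted p = 0.0194, median −0.05) and with the mean of a gene's probes (adjusted p = 0.0313, median −0.30). The protein C receptor PROCR fell by 1.29 (SE 0.112) and NOTCH3 by 0.70 (SE 0.119), and the efflux transporter ABCG2 rose by 0.71 (SE 0.124).

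Lists of the cell cycle, of p53 targets and of ribosome biogenesis did not pass as sets. Of 48 G1/S and DNA replication genes GINS3 rose by 0.85 (SE 0.0982) and 0 fell (median 0.11, camera adjusted p = 0.165), the same adjusted over the list alone, and this list passed upwards by fry (adjusted p = 0.0331). ORC1 at 0.45 and MCM5 at 0.37 did not pass. Of 65 G2/M and mitosis genes SPC24 rose by 0.56 (SE 0.114) and NCAPH fell by 0.61 (SE 0.0929), a sign that turned under normexp with the 75th percentile (0.15). The SPC24 call, at an adjusted p of 0.0498, ended under 13 of 18 alternatives (adjusted p from 0.00644 to 0.508 over all of them). The median of that list was 0.04 (camera adjusted p = 0.867) and 0 members passed adjusted over the list alone, PRC1 at 0.44 and HMMR at 0.36 among those that did not. Of 32 p53 target genes PMAIP1 fell by 1.19 (SE 0.189) and DDB2 by 0.66 (SE 0.0944), and 0 rose (median −0.05, camera adjusted p = 0.243). TNFRSF10A at −0.49 and TP53INP1 at 0.50 did not pass over all genes, and adjusted over the list alone 5 p53 targets fell and 3 rose. Of 45 ribosome biogenesis genes 0 passed either way (median −0.02, camera adjusted p = 0.244), with TSR1 at −0.39, NOP16 at −0.36, NOP14 at −0.31 and PPAN at 0.28, and this list passed downwards with normexp and the 75th percentile (adjusted p = 0.00207, median −0.05) and with no filter (adjusted p = 0.0311). Replication-dependent histone genes passed as a set on small differences: 0 of 22 members passed over all genes or over the list alone, the median was −0.17 and the camera adjusted p = 0.00527, against an adjusted p = 0.759 with an estimated correlation. Among its members with the lowest unadjusted p were H2BC21 at −0.43, H2AC6 at −0.39 (its other probe at 0.19) and H2BC3 at −0.26. The call of this set ended with fry (adjusted p = 0.322), spike-in scaling (adjusted p = 0.0956, median −0.42) and without knockdown replicate 2 (adjusted p = 0.107), and the median was −0.28 without knockdown replicate 1.

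Cholesterol synthesis and SREBP target genes were higher as a set. Of 34 measured members 3 rose and 0 fell, with a median of 0.32 (camera adjusted p = 0.00527), and adjusted over the list alone 12 rose. With an estimated correlation the set's adjusted p = 0.759. The SREBP regulator INSIG1 rose by 0.76 (SE 0.106), the synthase HMGCS1 by 0.54 (SE 0.0949) and the isomerase IDI1 by 0.48 (SE 0.0937), while ACSS2 at 0.45 did not pass. The calls of INSIG1, HMGCS1 and IDI1 each ended with any 1 array left out and with spike-in scaling (0.51, 0.29 and 0.24), and those of HMGCS1 and IDI1 also with the median in place of the 75th percentile. The call of the set also ended with fry (adjusted p = 0.155), normexp with the 75th percentile (adjusted p = 0.0797), no filter (adjusted p = 0.0584), without control replicate 1 (adjusted p = 0.0612) and without knockdown replicate 2 (adjusted p = 0.107). With spike-in scaling the median was 0.07 (adjusted p = 0.0497). Of 45 unfolded protein response and ATF4 target genes the cystine transporter SLC7A11 rose by 1.24 (SE 0.105), and ATF3 and the serine synthesis enzyme PHGDH fell, PHGDH by 1.92 (SE 0.226, or by 0.65 with normexp and the 75th percentile), with the same counts adjusted over the list alone. DDIT3 differed by −0.41 (adjusted p = 0.0648). The median of that list was 0.02, its mean −0.02 and its test pointed downwards (camera adjusted p = 0.664). Of 42 hypoxia and glycolysis genes 2 rose and 2 fell (median 0.10, camera adjusted p = 0.256), or 5 and 2 adjusted over the list alone, and the list passed upwards without control replicate 2 (adjusted p = 0.000842, median 0.22). The aldolase ALDOC rose by 1.30 (SE 0.249) and the lactate exporter SLC16A3 by 0.79 (SE 0.136), and ANGPTL4 fell by 1.38 (SE 0.120) and VEGFA by 0.56 (SE 0.104). Of 50 oxidative phosphorylation genes 0 passed either way (median 0.11, camera adjusted p = 0.243), with NDUFS7 at 0.38, ATP5F1A at 0.35, COX7B at 0.28 and COX5A at −0.46, and this list passed upwards without control replicate 2 (adjusted p = 0.0252, median 0.18). Of 19 H3K4 demethylases and readers 0 passed either way. Their median was −0.00074, their mean 0.03 and their test pointed downwards (camera adjusted p = 0.799), with ING4 at 0.37, SGF29 at 0.27, PHF2 at 0.25 and PHF8 at −0.32.

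Markers of other cell types were checked as lists. Of 13 measured haematopoietic markers CD14 fell by 1.33 (SE 0.0960) and the receptor CSF1R rose by 0.85 (SE 0.106), with the same counts adjusted over the list alone and a median of −0.01 (camera adjusted p = 0.812). SPI1 at 0.31 and CD68 at −0.31 did not pass. Of 8 measured endothelial markers 2 fell and 0 rose, with a median of −0.49 (camera adjusted p = 0.0163), and adjusted over the list alone 3 fell. With an estimated correlation this set's adjusted p = 0.586. The receptor KDR was at least 3.43-fold lower (−0.29 with normexp and the 75th percentile) and above background in the controls alone, and the junction protein ESAM fell by 1.68 (SE 0.143). ROBO4 at −0.63 and TEK at −0.90 did not pass over all genes. The call also ended with fry (adjusted p = 0.107), with normexp and the 75th percentile (adjusted p = 0.0861, median −0.07) and with no filter (adjusted p = 0.786, median 0.17). The test of this list pointed downwards, as did those of the junction, interferon-stimulated and chemokine lists, although 2 of its 8 members lay above 0. The medians of 13 lists changed sign between scalings, 0 of them among the 7 lists past the threshold. Besides the genes named so far with this limit, the calls of GATA3, SDC4, BIRC2, RECK, CFL2, FSCN1, NOTCH3, ABCG2, SPC24, NCAPH, DDB2, SLC16A3 and VEGFA ended when either knockdown array was left out, that of COL6A2 without knockdown replicate 1 and those of ITGB3, ALDOC and DMBT1 without knockdown replicate 2. With spike-in scaling the calls of TAGLN, GINS3, CSF1R, GATA3, BIRC2, RECK, ABCG2 and SLC16A3 ended, and with normexp and the 75th percentile those of ITGB3 (−0.19) and NOTCH3 (−0.10).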

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

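Of the processing alternatives, the common signal bar alone was chosen after the data were examined. The cause of a change was not tested unless given. ASH2L was lower under all 18 alternatives (−2.37 to −1.74), and its call ended under 3: no filter (−2.13, adjusted p = 0.0878) and each control array left out (range over the arrays left out −2.19 to −2.06). Rises numbered 339 with spike-in scaling, 3940 with normexp and the 75th percentile, 1236 with normexp and quantiles, 0 with no filter (27680 genes tested), 1583 with trend and robust settings and 1735 at an adjusted p under 0.10. Falls numbered 1984 with spike-in scaling, 0 with no filter, 1470 with trend and robust settings and 1607 at an adjusted p under 0.10. With arrays left out rises ranged from 0 to 744 and falls from 0 to 803. Spike-in scaling moved the median of all genes from 0.06 to −0.19, and normexp with the 75th percentile moved it to 0.13 and turned the sign of 142 called genes. The spike-in probes used differed unevenly between groups before scaling, from −0.55 to 0.10. The replicate numbers are not shown to pair the arrays (deviations of same-numbered arrays correlated at 0.0993, over 2 pairs); with a replicate block 867 genes were higher and 1201 lower. Slide and scan as a block were not run, since there was 1 slide and 1 scan.

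Of the 83 named genes that passed, 83 lost their call without either control array and with no filter, 19 and 21 without knockdown replicates 1 and 2, 14 with spike-in scaling and at most 6 under each other alternative. Under normexp with the 75th percentile 4 named genes turned, PHF8 to 0.011, NCAPH to 0.15, TEK to 0.12 and COL1A1 to 0.0021. Lists past the threshold numbered 0 with an estimated correlation, a test with 2 degrees of freedom that few lists can pass. Medians stay as they were there: junction genes −1.02, chemokines −0.84, interferon-stimulated genes −0.76, cholesterol genes 0.32, histone genes −0.17, basal markers −0.22 and endothelial markers −0.49. Fry ended the calls of chemokines (−0.84), cholesterol (0.32), histone (−0.17) and endothelial genes (−0.49). Normexp with the 75th percentile, where the median of all genes was 0.13, passed 12 lists but not cholesterol genes (0.28) or endothelial markers (−0.065). Spike-in scaling ended the call of histone genes (−0.42), and no filter those of cholesterol genes (0.32) and endothelial markers (0.17). With arrays left out the medians ranged from 0.26 to 0.39 (cholesterol), −0.28 to −0.13 (histones) and −0.29 to −0.22 (basal). Junction and interferon-stimulated genes passed in 18 of 19 list settings and chemokines in 17.

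Among lists that did not pass, the direction of the test turned as follows, with the list's median. G2/M genes turned under ranks, no filter and the filter on all arrays (0.036 each), the median scaling (−0.042) and normexp with the 75th percentile (0.016). H3K4 demethylases and readers turned with fry (−0.00074), spike-in scaling (−0.25) and normexp with quantiles (−0.0043). Haematopoietic markers turned with normexp and the 75th percentile (0.24), no filter (0.25) and the mean of probes (0.11). G1/S (0.076), hypoxia (0.079) and oxidative phosphorylation genes (0.066) turned with normexp and the 75th percentile, and TGF-beta targets with no filter (0.10). These medians stayed above 0, and the turns are relative to the median of all genes, 0.13 with normexp and the 75th percentile and 0.15 with no filter. The direction also turned without control replicate 1 (G2/M, hypoxia), control replicate 2 (H3K4 demethylases and readers, haematopoietic, actin, unfolded protein response) and knockdown replicate 2 (G2/M, haematopoietic). With arrays left out medians ranged from 0.031 to 0.040 (G2/M), −0.034 to 0.032 (H3K4 demethylases and readers), −0.069 to 0.084 (haematopoietic), −0.010 to 0.22 (hypoxia), −0.0041 to 0.021 (actin) and −0.019 to 0.068 (unfolded protein response).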

Other observations

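Genes of BMP signalling stood among the rises, and a list of 25 targets of BMP and of SMAD1, SMAD5 and SMAD9 was written after the largest rises had been seen, without looking at 22 of its members. SMAD9 rose by 1.93 (SE 0.0935), SMAD6 by 1.14 (SE 0.211), ID1 by 0.80 (SE 0.111) and SMAD7 by 0.55 (SE 0.107), beside ID3 and ATOH8. ID2 differed by 2.35 (SE 0.569) and did not pass (adjusted p = 0.0703). The BMP-binding protein BMPER fell by 1.61 (SE 0.115). Of the 14 unseen members that were measured, 3 rose and 1 fell, with a median of 0.36 and a camera p = 0.131 (0.354 with an estimated correlation). The test was set to count a p over 0.05 against a BMP response, which was too strict, since a p that misses the threshold excludes nothing, and the hypothesis stays open.

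Called genes lay next to each other more often than chance. Of 13770 tested genes ordered along the chromosomes of GRCh38.p14, 146 neighbouring pairs were called in the same direction, against 84.3 on average in 10000 permutations of the calls. Without neighbours whose symbols share a stem, 128 pairs remained, against an average of 79.0 and a highest permuted count of 115, so that 0% of the permutations gave as many. Permuting within bins of like brightness, added after the result was seen, gave an average of 78.1 and a highest count of 116. Runs of 3 or more, named after their values were seen, included IFIT2, IFIT3 and IFIT1 (lower), NECTIN1, TRIM29 and OAF (lower), and ATOH8, LOC284950 and ST3GAL5 (higher). Changes shared by neighbouring genes may therefore exist in these cells, as a hypothesis. Overlapping transcripts were not separated from neighbours.

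In the patterns weighed below, the tests of luminal markers and of the dimmer genes were chosen after the results were seen. Interferon-stimulated genes were lower in the knockdown, at a median of −0.76. A shift of all genes of like brightness is argued against: 0% of 10000 random lists matched on brightness had a median as low, and the lowest was −0.14. Whether the control cells had a raised interferon response, rather than the knockdown a lowered one, cannot be told apart, because the number of arrays of untransduced cells was 0. An effect of ASH2L loss and an effect of the hairpin on other transcripts stay open and untested.

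Epithelial junction genes were lower at a median of −1.02, and 0% of 10000 lists matched on brightness had a median as low (lowest −0.33), which argues against a shift of all genes of like brightness. Fewer cells of a luminal-like subpopulation in the knockdown culture could lower them. Luminal markers lay 0.70 above the junction genes, less than the spread of the luminal members (SD 0.80 over 17 genes). That spread is of single genes and not the uncertainty of the difference between the medians, which was not estimated. The test therefore cannot decide between fewer such cells and a fall in each cell. An effect of ASH2L loss stays open and untested.

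Falls of 2-fold or more outnumbered rises, 496 to 174, and over the same genes 608 to 251 and 560 to 236 without knockdown replicates 1 and 2 (608 to 495 and 561 to 608 with the genes kept only for the remaining knockdown array), while limma called 0 without either control array (4429 and 4831 genes at an unadjusted p under 0.05). The lowest ratio of falls to rises over the scaling and background alternatives was 3.29, with normexp and the 75th percentile. That setting raised the median of all genes from 0.06 to 0.13 but also changed the background correction. Quantile normalization (0.02), the median (−0.02) and spike-in scaling (−0.19) lowered that median, which favours falls. They could therefore not test whether another scaling would remove the excess of falls. Among genes brighter than the median the ratio was 2.88 (115 to 40, 95% exact binomial interval 1.99 to 4.23, which treats genes as independent), and 4.48 and 4.13 without knockdown replicates 1 and 2, which argues against the lower brightness of the knockdown arrays near the detection limit as the whole cause. Among the dimmer genes it was 2.84, and 3.04 (343 to 113, interval 2.45 to 3.79) with 1 scaled signal bar for all arrays as the filter and as a floor. With all arrays in the fit this argues against unequal detection as the whole cause there as well. The ratio among the dimmer genes depended on the filter, however. The genes kept only for the remaining knockdown array, which evened or turned the left-out counts above, were called among the dimmer genes alone. An effect of ASH2L loss and an effect of the hairpin on other transcripts stay open and untested.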
